A study of Mus musculus with 10 samples.

How the data were processed

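MC38 is a mouse colon carcinoma line that grows in C57BL/6J mice. Tumor cells carrying the dTomato fluorescent protein were sorted from tumors 21 days after implantation, with cells bearing CD45, the common leukocyte surface protein, gated out. RNA was taken with an RNeasy kit, and libraries of polyadenylated RNA were made with a NEBNext Ultra RNA kit, per the labels' protocols. There was 1 library per mouse, from 5 mice on a control diet and 5 on a high-fat diet. The composition of the diets, the time on diet and the sex of the mice are not given in the sources used here.

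The values are raw read counts per gene, which the authors deposited as whole numbers in a single table with 1 column per mouse. The submitters' processing notes name cutadapt 1.15, FastQC 0.11.5, BWA 0.7.12, DESeq2 1.24.0 and the mouse builds GRCm38 and mm10, with no roles. The counting program, annotation release, strand setting and treatment of reads with several equally good positions are not given in the sources used here. Because the strand setting is unknown, reads of a gene and of a partner on the opposite strand cannot be told apart. Among named genes, exons overlapped those of an opposite-strand partner for Cryab (Hspb2), Pfkm (Senp1), Cox6c (Vps13b), Pdia3 (Catsper2), Erap1 (Cast), Hspe1 (Hspd1), Arhgdib (Pde6h), Acaa1a (Myd88), Cxcl16 (Zmynd15), Il1b (Il1bos), Pdia6 (Atp6v1c2), Igfbp7 (Polr2b) and Cxcl10 (Art3), and Clec9a overlapped Clec1b on its own strand. Several others overlapped noncoding or predicted genes. BWA, if it placed the reads, is not a spliced aligner, and reads that cross exon junctions or fit several copies of a sequence can then be lost.

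The table held 53379 genes, and every entry was a gene identifier. Of these, 53274 matched the GENCODE M21 annotation of GRCm38 when the version suffix was ignored, and 50604 matched with the suffix. Symbols and coordinates were taken from that annotation. To find genes open to shared reads, overlapping windows of 50 bases were taken along each gene's longest annotated transcript. The percentage of windows found exactly in transcripts of other genes was recorded. Among genes named here this percentage was at least 12% for some: 72.2% for Eno1, 62.7% for Hspa1b, 51.3% for mt-Co1, 35.1% for H2-T22, 27.4% for Acot2, 26.1% for Me1, 22.8% for H2-Q4, 16.9% for Ldha, 16.3% for Acaa1a, 14.2% for Lyz2 and 12.0% for Fdps, and their counts are less certain for that reason. Gapdh had 26.9% of its windows shared and a mean of only 40.0 ± 12.1 CPM (counts scaled to a common library size; SD, n = 10), against 595 ± 86.4 for Tpi1, another glycolytic gene. Across 54 ribosomal protein genes the shared percentage ran from 0% to 82.5% and fell with expression (Spearman rho = -0.35 across genes, permutation p = 0.0101, genes not being independent replicates). Absolute levels of such genes should not be compared with those of other genes.

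Counts per library ran from 17050797 to 18653705 in control mice and from 16513388 to 17154050 in high-fat mice, and their means differed at p = 0.0317 in an exact two-sided permutation test. A count of 3, the upper limit that a count of 0 allows, corresponded to between 0.161 and 0.182 CPM. Such limits cover counting error only, since the reads carry no molecular identifiers. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom of any pair being 8.36, so all 10 were kept as separate replicates. Spearman correlations between libraries lay between 0.982 and 0.995.

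Before the data were examined, the tests, the alternatives, 38 gene lists, a panel of 25 genes and the rule for naming genes were fixed. Which lists are described member by member was partly settled later: the chemokine, checkpoint, TNF and NF-kB, unfolded protein and insulin lists were added to these after results were seen, so their named members were too. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter with diet as the group, robust quasi-likelihood fits with diet as the only term, a two-sided test of high-fat minus control, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 14337 genes, which held 99.9% of all counts. Standard errors of log2 fold changes were taken as the absolute change divided by the square root of the F statistic. Means ± SD are of TMM-scaled CPM over 5 mice unless stated otherwise. Where a gene's values are described without an adjusted p under 0.05, it did not pass.

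Gene lists with at least 5 tested members, 32 of the 38, were tested on log2 CPM (prior count 2) with camera of limma 3.58.1. Camera compares a list with all other genes and was run with a preset correlation between genes of 0.01 and adjustment over the 32 lists. The same test was run with the correlation estimated for each list, and fry, which tests whether a list moves by itself, was run as a companion. Members were also counted after adjustment over the list alone. Each list's mean log2 CPM per library was compared between diets with an exact two-sided permutation test, for which the smallest possible p is 0.00794. The named genes were the genes past the threshold with a mean log2 CPM of at least 1 (up to 12 per direction by size of change, predicted genes left out), up to 2 rising and 2 falling members of each list described, by unadjusted p, and the panel. Other members are named where a list had 5 or fewer that passed, and were then chosen after their values were seen. Some genes of the panel are not reported here. The difference between the mean distance between diets and within diets (distance being 1 minus Spearman rho over the tested genes) was tested by exact permutation over the 126 splits of the libraries, one-sided.

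The gene test was checked on counts simulated from the means and library sizes of these 10 libraries for the comparison of 5 high-fat with 5 control mice. Over the 14206 genes run, edgeR recovered 76.0% of 100 genes changed 2-fold and 57.0% of 100 changed 1.5-fold, with 10 false calls. DESeq2 1.42.0 recovered 81.0% and 61.0% with 34 false calls, and limma-voom 75.0% and 55.0% with 7. In the simulated list test, camera found a list of 30 genes shifted 1.3-fold and called 0 of 30 unshifted lists. Genes were simulated independently, so this checks the code and says nothing of false calls among correlated genes. Across 100 splits of the real libraries camera called between 1 and 20 lists.

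Alternatives chosen beforehand covered other scalings, no filter and a stricter one (CPM above 1 in 5 libraries), DESeq2, limma-voom with sample weights, a surrogate variable (sva 3.50.0), library size as a covariate, the mouse number as a block, other thresholds, and leaving out each mouse. Alternatives added after seeing the data were the level of macrophage genes or of pan-leukocyte genes as a covariate, the fit without control mice 3 and 4, which had the most leukocyte transcripts, and permutation and fry calls for lists. Control mice 3 and 4 also stood highest of the controls on the interferon, MHC class I, cholesterol, mitochondrial and T and NK cell lists. They stood lowest of the controls on the amino acid, hypoxia, unfolded protein, NRF2 and lipid uptake lists. Leaving them out therefore widens the differences of all these lists by construction and is no independent support for them. The macrophage and pan-leukocyte levels were highest in the same mice, so counts with these levels as covariates are no independent support either. The lists for neutrophils, B and plasma cells, adipocytes, keratinocytes, erythroid cells and Y-linked genes had too few expressed members to test.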

Results

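Gene expression was measured by RNA sequencing in MC38 colon carcinoma cells sorted from the tumors of 5 control-diet mice and 5 high-fat-diet mice, 21 days after implantation. The sort kept cells that carried the dTomato marker and lacked CD45. Control libraries held between 17050797 and 18653705 counts and high-fat libraries between 16513388 and 17154050, and 14337 genes were expressed well enough to test. The single comparison in the design was between the diets, and asks how tumor cells differ when the host is fed a high-fat diet. Changes are given as high-fat minus control, coordinates are those of GRCm38, and each value rests on 5 mice per diet.

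On the high-fat diet the tumor cells had more transcript of Stra6, the cell-surface receptor through which retinol enters cells. The level of Stra6 was 13.2 ± 2.45 CPM (SD, n = 5) in control mice and 32.3 ± 3.00 CPM (SD, n = 5) in high-fat mice, a 2.44-fold rise. Transcripts of Sema3c, a secreted semaphorin, fell from 90.4 ± 11.6 to 41.7 ± 10.3 CPM, and those of Slc5a4a, a member of the sodium/glucose cotransporter family, fell from 8.76 ± 3.66 to 2.69 ± 0.510 CPM. In total 9 genes passed the threshold, 6 higher and 3 lower on the high-fat diet, and for each of the 9 all 5 high-fat libraries lay beyond all 5 control libraries.

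**Figure D1:**
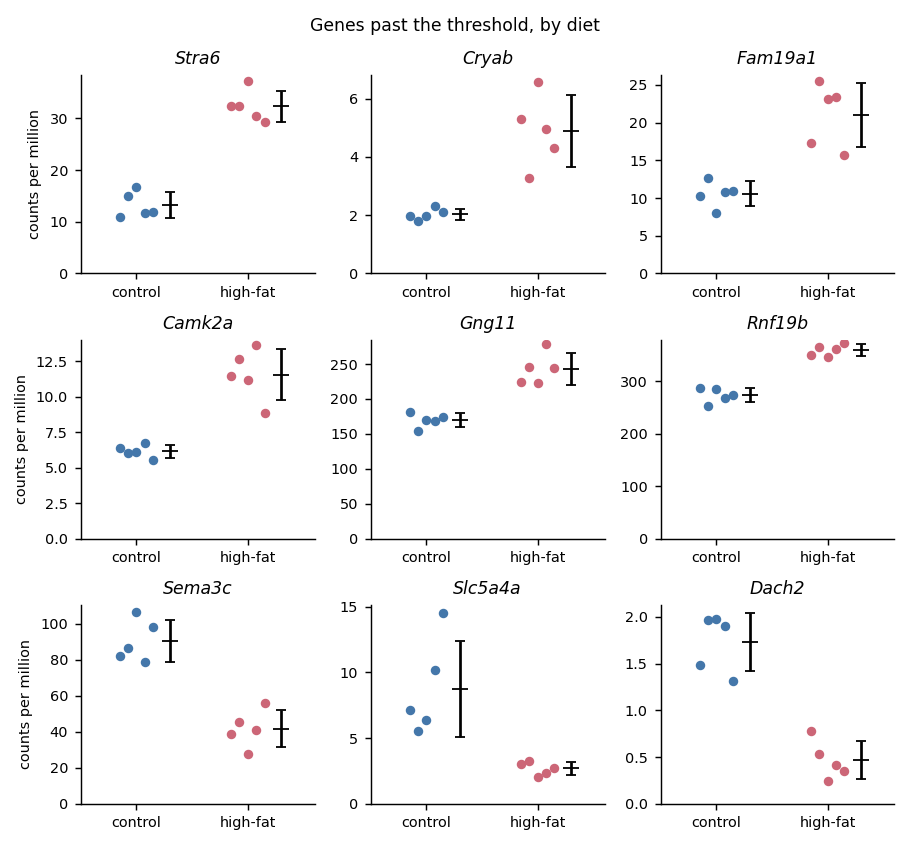
CPM (vertical axes, from 0) of the 9 genes past the threshold in each control (blue) and high-fat (red) mouse, with mean and SD (n = 5). The groups do not overlap for any of the 9, and Stra6 reaches at most 16.7 CPM in control mice and at least 29.4 CPM in high-fat mice.

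Stra6 (ENSMUSG00000032327.14, chromosome 9, 58063788 to 58153996) had a log2 change of 1.29 (SE 0.12) and an adjusted p of 0.00137 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cryab, the small heat shock protein alpha-B-crystallin (chromosome 9, 50751325 to 50756636), rose by 1.26 (SE 0.19) on the log2 scale, from 2.03 ± 0.194 to 4.89 ± 1.22 CPM; its exons overlap Hspb2 on the opposite strand. Fam19a1, which encodes a secreted chemokine-like protein (chromosome 6, 96113154 to 96657198), rose by 0.99 (SE 0.15), and Camk2a, a calcium/calmodulin-dependent kinase (chromosome 18, 60925618 to 60988152), rose by 0.91 (SE 0.12). Smaller rises at higher expression were those of the G protein subunit Gng11 (chromosome 6, 4003904 to 4008445), from 170 ± 9.91 to 243 ± 22.7 CPM, and of the E3 ubiquitin ligase Rnf19b (chromosome 4, 129058271 to 129085886), from 274 ± 13.8 to 360 ± 11.2 CPM. Slc5a4a (chromosome 10, 76147451 to 76189265) fell by 1.70 (SE 0.26) on the log2 scale and Sema3c (chromosome 5, 17574281 to 17730268) fell by 1.12 (SE 0.16). The remaining gene, the transcription factor gene Dach2 (chromosome X, 113297510 to 113836386), lay below the expression minimum for named genes and is named after its values were seen; it fell from 1.73 ± 0.310 to 0.464 ± 0.203 CPM. The edgeR adjusted p of the 8 genes other than Stra6 lay between 0.0369 for Camk2a and 0.0409 for Rnf19b.

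At an unadjusted p under 0.05, 782 genes were higher and 949 lower, 1731 in all, where 717 would be expected with no effect. The groups did not overlap for 312 genes, 2.18% of those tested against 0.794% by chance. Libraries of different diets were farther apart than libraries of the same diet (mean 1 minus Spearman rho of 0.0127 against 0.0102, exact one-sided permutation p = 0.0238 over 126 splits). This p was 0.0714 without control mouse 4, 0.0556 without high-fat mouse 3 and 0.0536 without control mice 3 and 4, all by exact permutation. The number of genes past the threshold moved with single libraries: in edgeR it was 1, 4, 27, 2 and 1 without control mice 1 to 5 in turn, and 21, 2, 2, 1 and 13 without high-fat mice 1 to 5. Control libraries were larger on average, and with library size as a covariate the edgeR count was 0 (817 genes at an unadjusted p under 0.05). It was 316 with DESeq2 (106 higher and 210 lower) and 740 with limma-voom (345 and 395). With a surrogate variable it was 180 (46 and 134). Without control mice 3 and 4, an alternative chosen after the data were seen, it was 276 (120 and 156). In these 4 fits more genes were called lower than higher, unlike the 6 and 3 reported.

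The list of genes induced by interferon rose on the high-fat diet in camera's test (adjusted p = 8.8e-24, and adjusted p = 0.420 with an estimated correlation). Some other splits of the libraries gave this list a smaller unadjusted camera p (3.6e-35, 8.3e-27 and 1.1e-26) than diet did (2.7e-25). The splits with 3.6e-35 and 1.1e-26 only exchanged control mouse 4 for high-fat mouse 1 or 4, and so kept most of the diet contrast. The split with 8.3e-27 set control mice 1, 2 and 5 with high-fat mice 1 and 2, as mixed by diet as 5 against 5 allows. By that split, a small camera p with the preset correlation is not particular to diet. Of 45 members, 44 had a positive change, and the list mean was higher by 0.64 (SE 0.22) log2 CPM, at 5.72 ± 0.47 in control and 6.36 ± 0.17 in high-fat mice, which is 1.56-fold. Bst2, which tethers budding virus to the cell surface, stood at 154 ± 32.9 and 233 ± 21.2 CPM, and the nucleic acid sensor Zbp1 at 195 ± 36.7 and 292 ± 31.7 CPM. The T cell chemokine Cxcl10 stood at 167 ± 65.2 and 256 ± 22.3 CPM, in control and high-fat mice. Socs1, an inhibitor of the pathway, was the only member with a negative change, of -0.03 (SE 0.11).

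No interferon-stimulated gene passed the threshold over all genes tested in edgeR, where 34 had an unadjusted p under 0.05 and 29 of the 45 passed when adjusted over the list alone, all higher. Over all genes 8 passed with DESeq2 and 18 with limma-voom. The exact two-sided permutation test of the list mean gave p = 0.0238, or 0.127 adjusted over the 32 lists. The T and NK cell list had a mean difference of 0.70 (SE 1.02) on the same diet and the pan-leukocyte list one of -0.76 (SE 0.69). With the pan-leukocyte level as a covariate, an alternative chosen after the data were seen, 40 of the 45 genes passed over all genes tested. Without control mice 3 and 4, 33 passed. Those mice had the highest interferon list means of the controls (6.15 and 6.20 log2 CPM), so leaving them out widens the difference by construction. The pan-leukocyte level was lower on the high-fat diet, and adjusting for it also raised the difference. Neither count is independent support.

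The MHC class I antigen presentation list rose in camera's test (adjusted p = 0.00018, and adjusted p = 0.491 with an estimated correlation), by a mean of 0.16 (SE 0.09) log2 CPM with 19 of 21 members higher. In edgeR none of the 21 passed, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. DESeq2 called 1 over all genes and 3 over the list alone, and limma-voom 5 and 10, all higher. With the macrophage level, with the pan-leukocyte level and without control mice 3 and 4, in that order, edgeR called 5, 5 and 4 over all genes and 8, 9 and 9 over the list alone, with 21 of 21 higher in each. Control mice 3 and 4 were highest of the controls on this list (8.67 and 8.60 log2 CPM) and on both covariates. These counts are therefore no independent support. Pdia3, a chaperone of the peptide-loading complex whose exons overlap Catsper2 on the opposite strand, had the smallest p, at 1608 ± 176 and 2009 ± 137 CPM in control and high-fat mice. Among the abundant components, B2m had a log2 change of 0.05 (SE 0.10) and H2-K1 of 0.03 (SE 0.09). H2-T22 was at 132 ± 23.5 and 170 ± 14.8 CPM. Cd274, which encodes PD-L1, was at 59.0 ± 23.1 and 82.9 ± 15.2 CPM (edgeR adjusted p = 0.472).

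**Figure D2:**
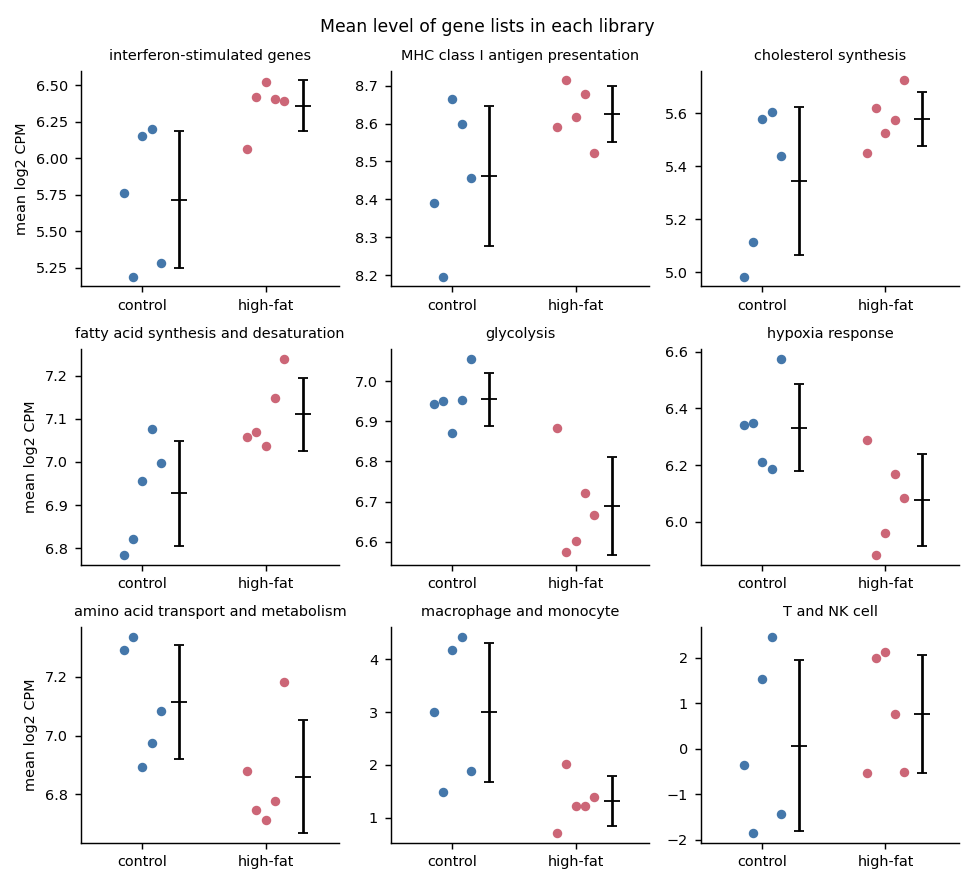
Mean log2 CPM of the members of 9 gene lists (vertical axes, each with its own range) in each control (blue) and high-fat (red) mouse, with mean and SD (n = 5). The interferon-stimulated list runs from 5.19 to 6.20 in control mice and from 6.06 to 6.52 in high-fat mice, and the macrophage list from 1.49 to 4.43 and from 0.71 to 2.02.

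Chemokine and cytokine genes went in both directions. In edgeR 7 of 26 passed as higher and 5 as lower over the list alone. Among the higher were Il15, a cytokine that sustains NK and memory T cells, at 6.21 ± 1.36 and 10.1 ± 1.87 CPM in control and high-fat mice, and Il34, a ligand of the CSF1 receptor, at 94.8 ± 11.7 and 119 ± 8.68 CPM. The lower ones included Cxcl16, at 7.15 ± 5.29 and 1.62 ± 0.453 CPM, and the inflammatory cytokine Il1b, at 4.63 ± 2.79 and 1.40 ± 0.458 CPM. Ccl2, which recruits monocytes, was at 275 ± 65.6 and 380 ± 47.6 CPM, and Cxcl1 was at 63.1 ± 8.26 and 76.6 ± 24.1 CPM. The list as a whole did not pass camera (adjusted p = 0.891), and its mean difference of -0.05 had the opposite sign to the test's direction. Fry's test for change in either direction gave an adjusted p of 2.4e-05. Macrophage genes were lower on the same diet as Cxcl16, Il1b and, in the list of checkpoint genes, Arg1.

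Of 15 immune checkpoint genes, 2 passed as higher and 4 as lower over the list alone (camera adjusted p = 0.680). The higher ones were Cd200, at 11.3 ± 3.58 and 18.4 ± 2.36 CPM, and the tryptophan-degrading enzyme Ido1, at 1.83 ± 0.342 and 3.42 ± 1.75 CPM. The lower ones were the arginine-degrading enzyme Arg1 (9.77 ± 6.05 and 1.32 ± 0.544 CPM), the AMP-degrading ectoenzyme Nt5e (1.75 ± 0.450 and 0.811 ± 0.241 CPM), the prostaglandin synthase Ptgs2 and Cd276. In the TNF and NF-kB list (camera adjusted p = 0.213), 5 of 22 passed as higher over the list alone, among them Vcam1 (319 ± 45.9 and 420 ± 55.4 CPM) and Nfkbie (47.4 ± 3.41 and 57.2 ± 3.82 CPM). Ptgs2 and Cxcl2 passed as lower, Ptgs2 at 230 ± 40.2 and 162 ± 25.4 CPM.

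All 24 genes of cholesterol synthesis and uptake had positive changes and the list rose in camera's test by a mean of 0.23 (SE 0.13) log2 CPM (adjusted p = 2.1e-06, and adjusted p = 0.491 with an estimated correlation). Fdps, an enzyme of isoprenoid synthesis, had a log2 change of 0.55 (SE 0.18), and Dhcr7, which makes cholesterol from its last precursor, was at 72.9 ± 13.5 and 92.2 ± 7.07 CPM. Genes of fatty acid synthesis and desaturation rose in camera's test by 0.18 (SE 0.07), with 13 of 14 higher (adjusted p = 0.00034, and adjusted p = 0.426 with an estimated correlation). The desaturase Fads2 was at 174 ± 35.9 and 239 ± 34.4 CPM, Scd2 at 1845 ± 334 and 2439 ± 283 CPM, and Scd1 at 379 ± 67.9 and 462 ± 65.7 CPM. Fasn was at 663 ± 86.5 and 687 ± 59.0 CPM, and Me1 was the member with a negative change, of -0.36 (SE 0.13). In edgeR no gene of either list passed, over all genes or adjusted over the list alone, and 5 cholesterol and 7 fatty acid synthesis genes had an unadjusted p under 0.05. DESeq2 called 0 genes of either list over all genes and, over the list alone, 0 cholesterol and 5 fatty acid synthesis genes. Limma-voom called 3 and 6 over all genes, and 13 and 10 over the list alone. With the macrophage level as a covariate, with the pan-leukocyte level and without control mice 3 and 4, in that order, edgeR called 11, 6 and 15 cholesterol genes and 9, 7 and 9 fatty acid synthesis genes higher over the list alone, and 2, 3 and 2 and 0, 1 and 2 over all genes. Control mice 3 and 4 were highest of the controls on the cholesterol list and on both covariates, so its counts here are no independent support.

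Genes of lipid uptake, storage and lipolysis fell in camera's test, by a mean of 0.25 (SE 0.07) log2 CPM, with 10 of 16 lower (adjusted p = 0.0169, and adjusted p = 0.420 with an estimated correlation). Over the list alone 5 passed as lower: Vldlr, a receptor for triglyceride-rich lipoproteins, Dgat2, which completes triglyceride synthesis, Fabp4, Pnpla2 and Gpat3. Vldlr was at 130 ± 21.1 and 85.1 ± 9.57 CPM, and Dgat2 had a log2 change of -1.04 (SE 0.24). Lpin1 passed as higher, with a log2 change of 0.39 (SE 0.13), and the lipid droplet protein gene Plin2 had a log2 change of -0.34 (SE 0.19). Without control mouse 5 camera's adjusted p for this list was 0.0543. Adipocyte genes had between 814 and 1130 counts in control libraries and between 626 and 779 in high-fat libraries, and the macrophage list fell on the same diet. The adipocyte list shares members with this list, Fabp4 and Pnpla2 among them, so its lower counts partly restate the same genes.

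The list of fatty acid oxidation and PPAR targets did not pass camera (adjusted p = 0.218, and 0.0400 without control mouse 4), with 12 of 28 members higher and 16 lower. Acsl1, which activates fatty acids, Acot2 and Fabp4 passed as lower over the list alone, Acsl1 at 30.2 ± 3.44 and 24.2 ± 0.775 CPM. The oxidation enzyme genes Acadm and Acaa1a had positive changes of 0.22 (SE 0.07) and 0.32 (SE 0.10). Cpt1a, the gate of mitochondrial fatty acid entry, had a log2 change of -0.15 (SE 0.10, edgeR adjusted p = 0.607), and the PPAR target Angptl4 one of -0.62 (SE 0.22, edgeR adjusted p = 0.276). Cd36, Pdk4 and Lepr were below the expression filter, with 67, 17 and 41 counts over all 10 libraries, and were not tested.

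Glycolysis genes fell in camera's test, by a mean of 0.27 (SE 0.06) log2 CPM, with 20 of 22 lower (adjusted p = 4.2e-07, and adjusted p = 0.420 with an estimated correlation). Eno1, much of whose sequence is shared with other genes, was at 311 ± 40.5 and 240 ± 32.1 CPM in control and high-fat mice, Aldoc at 1.32 ± 0.514 and 0.551 ± 0.230 CPM, and Ldha, which makes lactate, at 1026 ± 116 and 828 ± 151 CPM. Pfkm and the second gene identifier carrying the symbol Aldoa were the members with positive changes, of 0.10 (SE 0.09) and 0.02 (SE 0.20). Genes of the hypoxia response fell with them, by 0.26 (SE 0.10), with 19 of 22 lower (adjusted p = 8.1e-06, and adjusted p = 0.421 with an estimated correlation). Over the list alone 5 passed, all lower: the carbonic anhydrase Car9, a standard marker of hypoxia, Higd1a, Stc2, Pdk1 and Egln1. Car9 was at 39.3 ± 9.38 and 22.5 ± 3.89 CPM, while Vegfa, at 395 ± 53.7 and 377 ± 31.6 CPM, and Egln3, at 132 ± 26.7 and 159 ± 25.0 CPM, did not pass. The macrophage list, described further on, fell on the same diet. In edgeR no glycolysis gene passed over the list alone and no gene of either list over all genes, with 12 glycolysis and 8 hypoxia genes at an unadjusted p under 0.05. For glycolysis DESeq2 called 0 over all genes and 3 over the list alone, and limma-voom 2 and 10. For hypoxia DESeq2 called 1 and 8, and limma-voom 3 and 5, all lower. EdgeR with the macrophage level, with the pan-leukocyte level and without control mice 3 and 4 called 8, 13 and 2 glycolysis genes and 13, 13 and 9 hypoxia genes lower over the list alone, and 2, 3 and 0 and 5, 7 and 2 over all genes. Control mice 3 and 4 stood lowest of the controls on the hypoxia list (6.21 and 6.19 log2 CPM). Leaving them out therefore widens its fall by construction. Pdk1 and Slc2a1 are in both lists.

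Nuclear-encoded genes of oxidative phosphorylation rose in camera's test by a mean of 0.06 (SE 0.07) log2 CPM, with 39 of 53 higher (adjusted p = 0.00817, and adjusted p = 0.693 with an estimated correlation). Cox6c, at 89.3 ± 6.67 and 112 ± 4.15 CPM, was the member that passed over the list alone. Its exons overlap Vps13b on the opposite strand. Camera's adjusted p was 0.119 without control mouse 4, 0.246 without high-fat mouse 1 and 0.300 without high-fat mouse 5. With the macrophage level as a covariate, with the pan-leukocyte level and without control mice 3 and 4, this list did not pass camera. In that order 26, 29 and 33 of the 53 genes were higher, and camera's direction reversed with the macrophage level. All 7 mitochondrially encoded transcripts had positive changes, with a mean rise in camera's test of 0.58 (SE 0.39) (adjusted p = 0.00366, and adjusted p = 0.509 with an estimated correlation). mt-Nd1 was at 2201 ± 801 and 3566 ± 1029 CPM and mt-Co1 at 3040 ± 946 and 4675 ± 2014 CPM, so the spread within each diet was large. In edgeR none of the 7 passed over the list alone, but all 7 did as higher with the macrophage level as a covariate, with the pan-leukocyte level and without control mice 3 and 4, with median log2 changes of 1.40, 0.98 and 0.97 against 0.59, and over all genes 1, 6 and 0 passed. Control mice 3 and 4 were highest of the controls on these transcripts and on both covariates, so these counts are no independent support.

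Genes of amino acid transport and metabolism fell in camera's test, by a mean of 0.25 (SE 0.12) log2 CPM, with 24 of 25 lower (adjusted p = 4.2e-07, and adjusted p = 0.491 with an estimated correlation). Slc7a11, the cystine importer, was at 35.0 ± 12.4 and 16.8 ± 2.36 CPM, and Pycr1, which makes proline, at 41.2 ± 6.62 and 30.5 ± 3.32 CPM. These and Slc1a4 passed over the list alone in edgeR. Over the list alone DESeq2 called 3 and limma-voom 21 of the 25 lower, and edgeR called 13 with the macrophage level as a covariate, 14 with the pan-leukocyte level and 16 without control mice 3 and 4. Those mice stood lowest of the controls on this list (6.89 and 6.97 log2 CPM), which widens the fall without them by construction. These edgeR counts are therefore no independent support. The antioxidant genes under NRF2 fell by 0.17 (SE 0.07), with 21 of 27 lower (adjusted p = 0.00146, and adjusted p = 0.491 with an estimated correlation), and Slc7a11, the glutathione synthesis gene Gclc (36.5 ± 2.94 and 29.8 ± 2.14 CPM) and Hmox1 passed over the list alone in edgeR, where DESeq2 called 7 lower and limma-voom 11 lower and 1 higher. MYC targets and nucleolar genes fell by 0.09 (SE 0.10) in camera's test, with 22 of 28 lower (adjusted p = 0.0185, and adjusted p = 0.693 with an estimated correlation), and in edgeR no member passed, with 4 at an unadjusted p under 0.05. DESeq2 called 0 members, and limma-voom 4 over all genes and 13 over the list alone, all lower. Ncl was at 1086 ± 88.8 and 905 ± 139 CPM and Myc itself at 223 ± 48.8 and 170 ± 41.9 CPM. Without 6 of the 10 mice, each left out in turn, the MYC list no longer passed, with the highest adjusted p, 0.191, without high-fat mouse 3.

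The unfolded protein and integrated stress response list did not pass camera (adjusted p = 0.0986), and its members went both ways. The endoplasmic reticulum chaperone genes Pdia4 (326 ± 25.7 and 414 ± 47.5 CPM), Pdia6 (345 ± 26.5 and 435 ± 51.9 CPM) and Creld2 passed as higher over the list alone. Vldlr, Slc7a11, Aldh1l2, Sesn2 and Trib3, all of them known targets of ATF4 or of amino acid stress, passed as lower, all in edgeR. Slc7a11 is also in the amino acid and NRF2 lists, and Vldlr in the lipid uptake list. Slc3a2, Slc7a5, Asns, Psat1, Phgdh, Shmt2 and Mthfd2 are in the amino acid list too. The falls of these lists are therefore partly the same genes. DESeq2 called 6 higher and 9 lower over the list alone, and limma-voom 8 and 17. Camera gave this list an adjusted p of 0.00708 without control mouse 3, 0.0380 without control mouse 4, 0.0333 without high-fat mouse 1 and 0.00747 without high-fat mouse 5. Insulin and IGF signalling genes did not pass camera (adjusted p = 0.0799, and 0.0406 without high-fat mouse 2) and in edgeR none passed over the list alone, with 4 at an unadjusted p under 0.05. Over the list alone DESeq2 called 1 higher and 2 lower, and limma-voom 1 and 3. Irs2, an insulin receptor substrate, was at 32.5 ± 2.12 and 23.9 ± 4.78 CPM, Igfbp6 at 92.5 ± 16.3 and 116 ± 5.56 CPM, and Igf1r at 68.0 ± 5.22 and 66.3 ± 4.25 CPM.

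Other lists that did not pass camera were cell proliferation (adjusted p = 0.879, with Mki67 at 198 ± 18.2 and 217 ± 42.6 CPM), cytosolic ribosomal proteins (0.891), p53 targets and apoptosis (0.926), immediate early and dissociation-response genes (0.199), epithelial identity (0.914) and mesenchymal and extracellular matrix genes (0.265), all camera adjusted p-values. The direction of camera's test and the sign of the mean difference disagreed for cell proliferation, where the mean difference was -0.00. Leaving out high-fat mouse 2 brought camera's adjusted p to 0.0451 for cell proliferation, 0.0365 for immediate early genes and 0.0132 for mesenchymal genes, and leaving out high-fat mouse 1 brought it to 0.0350 for immediate early genes.

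**Figure D3:**
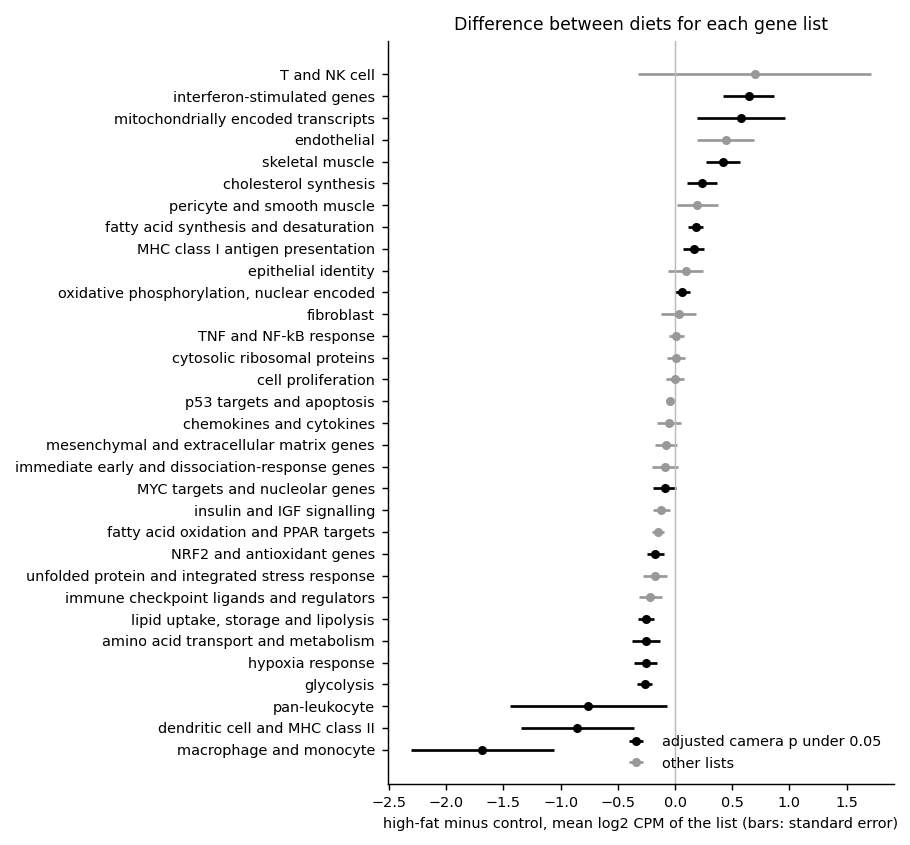
Difference in mean log2 CPM between diets, high-fat minus control, for the 32 gene lists (points, with standard errors over 5 mice per diet as bars); black marks an adjusted camera p under 0.05 with the preset correlation. The macrophage list lies farthest below 0, at -1.69, and the T and NK cell list farthest above, at 0.70 with a standard error of 1.02.

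Transcripts of macrophages were present in every library in spite of the CD45 gate, and were lower on the high-fat diet. All 19 measured macrophage and monocyte genes had negative changes, and the list fell in camera's test by a mean of 1.69 (SE 0.63) log2 CPM (adjusted p = 4.6e-14, and adjusted p = 0.420 with an estimated correlation). In edgeR 18 passed over the list alone and 0 over all genes, with 18 at an unadjusted p under 0.05. DESeq2 called 18 over the list alone and 12 over all genes, limma-voom 11 and 2, and edgeR without control mice 3 and 4 called 11 and 1. Lyz2, the macrophage lysozyme, was at 34.1 ± 20.8 CPM in control and 7.03 ± 1.53 CPM in high-fat mice, and the mannose receptor Mrc1 at 3.04 ± 2.21 and 0.382 ± 0.211 CPM. Spp1, which macrophages and tumor cells both make, was at 114 ± 52.7 and 61.8 ± 24.1 CPM. It did not follow the macrophage list among the controls, at 42.4 CPM in control mouse 3 and 147 CPM in control mouse 2. Their macrophage list means were 4.17 and 1.49 log2 CPM. Much of the spread of the list came from control mice 3 and 4, whose list means of 4.17 and 4.43 were the highest. Without them the difference was -0.82 (SE 0.43).

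Dendritic cell and MHC class II genes fell in camera's test by a mean of 0.85 (SE 0.49) log2 CPM, with 8 of 9 lower and 6 past the threshold over the list alone in edgeR (adjusted p = 0.00265, and adjusted p = 0.491 with an estimated correlation). DESeq2 also called 6 over the list alone, while limma-voom called 0, and edgeR called 0 without control mice 3 and 4 or with the pan-leukocyte level as a covariate. Cd74, the invariant chain of MHC class II, was at 142 ± 125 and 32.7 ± 11.7 CPM. Pan-leukocyte genes fell by 0.76 (SE 0.69), with 10 of 10 lower (adjusted p = 0.010, and adjusted p = 0.619 with an estimated correlation), and Arhgdib passed over the list alone in edgeR, where limma-voom called 0 genes. Ptprc, the gene of CD45, was at 9.58 ± 9.82 and 4.49 ± 3.59 CPM (edgeR adjusted p = 0.670). Without control mice 3 and 4 the dendritic cell list no longer passed (adjusted p = 0.422) and the pan-leukocyte list turned to a positive direction (adjusted p = 0.799). Leaving out single mice, the pan-leukocyte list did not pass without control mouse 3 or 4 or high-fat mouse 1 or 5 (camera adjusted p between 0.0782 and 0.146).

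T and NK cell genes did not pass camera, at a mean of 0.07 ± 1.88 and 0.77 ± 1.29 log2 CPM (adjusted p = 0.220, and 0.0148 without control mouse 4), and their median log2 change in edgeR was 0.20. In alternatives chosen after the data were seen it was 4.27 with the macrophage level as a covariate, 2.50 with the pan-leukocyte level and 2.84 without control mice 3 and 4, where 6 of 6, 6 of 6 and 5 of 5 passed as higher over the list alone and 3, 5 and 0 over all genes. Control mice 3 and 4 had the highest T and NK cell list means of the controls (1.55 and 2.47), so leaving them out raises this change by construction. The macrophage and pan-leukocyte levels were lower on the high-fat diet, so these shifts depend on the choice of covariate and are no independent support. The T and NK cell genes averaged 0.42 log2 CPM over the 10 libraries. As T and NK cells make interferon, their level bears on the interferon-stimulated list. Skeletal muscle genes rose in camera's test by 0.42 (SE 0.15), with 5 of 5 higher (adjusted p = 0.0304, and adjusted p = 0.420 with an estimated correlation); Tnni2, a troponin of fast muscle, had a log2 change of 0.61 (SE 0.27), and the list did not pass without control mouse 3 or high-fat mouse 1 or 3 (camera adjusted p between 0.0621 and 0.0916). Endothelial genes (adjusted p = 0.0885, but 0.00194 without control mouse 4 and 0.0406 without high-fat mouse 2), pericyte and smooth muscle genes (0.116) and fibroblast genes (0.913) did not pass camera. Counts over all members were 115 in control and 31 in high-fat libraries for neutrophil genes, 414 and 331 for B and plasma cell genes, 1163 and 1190 for keratinocyte genes, 4765 and 3440 for adipocyte genes and 380 and 81 for erythroid genes. Of the erythroid counts 295 came from control mouse 5, without which control libraries held 85, and of the neutrophil counts 48 came from control mouse 4, without which they held 67. The 7 Y-linked genes had 0 counts in every library.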

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

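The tests with the T and NK cell level as a covariate and those without control mice 3 and 4 were chosen only after the results were seen; the bound for the macrophage list without those mice, and how the T and NK cell test was read, were changed after their values were seen.

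Of 274 groups of 5 libraries examined, 10 (3.65%) had a library far from the rest, where chance gives about 1 in 20. Control mouse 4 had the highest Cxcl2 (2.22 CPM) and Igfbp7 (4.91 CPM) and the lowest Igf1r (59.1 CPM) of its group. Pdk4 was highest in control mouse 2 (0.477 CPM). Lepr was highest in control mouse 3 (0.292 CPM) and in high-fat mouse 3 (0.794 CPM) of their groups. High-fat mouse 5 had the highest Ncl (1148 CPM), Myc (243 CPM) and Cxcl10 (295 CPM) of its group. The interferon-stimulated list was lowest in high-fat mouse 1, at a mean of 6.06 log2 CPM.

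Among 100 splits of the 10 libraries into 5 and 5, 4 gave at least the 9 genes that diet gave in edgeR, the real split included. That share is under 0.05, but not all of the 126 possible splits were drawn, so chance cannot be excluded. With diet as the grouping the count was 1 without control mouse 1, control mouse 5 or high-fat mouse 4, and 0 with library size as a covariate. The other splits that reached 9 genes gave 21, 411 and 860. Those with 21 and 411 only exchanged control mouse 3 for high-fat mouse 5 and for high-fat mouse 1, and so kept most of the diet contrast. The highest set control mice 1, 2 and 5 with high-fat mice 1 and 5 against the rest, which points to a structure of the samples other than diet. In that order the T and NK cell list means of these mice were -0.36, -1.85, -1.44, -0.54 and -0.51. The rest lay between 0.77 in high-fat mouse 4 and 2.47 in control mouse 4. Whether T and NK cell content made this split was not tested. For the 16 gene lists past the threshold, 11 of the 100 splits gave as many, with 20 as the highest other, so chance cannot be excluded.

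Interferon-stimulated genes were higher on the high-fat diet by 0.64 log2 CPM. The pan-leukocyte level was lower on the high-fat diet (-0.76, SE 0.69), so no higher total leukocyte content was seen there by this marker. With that level as a covariate the difference was 0.88 (SE 0.07). Without control mice 3 and 4, where the level differed by 0.13 (SE 0.56), it was 0.92 (SE 0.09) against 0.95 unadjusted. A covariate lower on the high-fat diet, or so alike in both, could hardly shrink the difference. The adjusted values therefore do not exclude leukocyte RNA. A single library was argued against by the lowest difference of 0.51 with 1 mouse left out. T and NK cells, or interferon made by them, cannot be told apart from a response without them: the difference with their level as a covariate was 0.51 (SE 0.11), but their 6 genes averaged 0.42 log2 CPM, and a covariate resting on so few counts can adjust too little. The adjusted p of 0.420 with an estimated correlation leaves the pattern itself open.

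Macrophage and monocyte genes were lower on the high-fat diet by 1.69 on the log2 scale. Their members rose and fell together within the diets (median pairwise correlation 0.90), which is consistent with differing carry-over of macrophages or their RNA through the CD45 gate. Without control mice 3 and 4 the difference was -0.82 (SE 0.43), which met the bound first set for those libraries as the cause; the further demand that it do so by more than its SE was added after the value was seen. Those libraries were picked for their high leukocyte level, so leaving them out lowers the difference by construction, and their share in it cannot be told apart from an effect of diet. Fewer macrophages in the tumors of high-fat mice could give the same values, and was not tested.

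Glycolysis and hypoxia genes together were lower on the high-fat diet by a joint difference of -0.26 log2 CPM. Less macrophage RNA was argued against by the difference of -0.40 (SE 0.08) with the macrophage level as a covariate. With the immediate early level as a covariate the joint difference was -0.24 (SE 0.08). That level differed between diets by only -0.08 (SE 0.11), so no difference in handling was seen by this marker. A covariate so alike in both diets could change the joint difference little, so the adjusted value does not exclude handling. Better oxygen supply or another effect of the diet on the tumor cells may account for it and was not tested.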

How the results depend on the processing

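The alternatives with macrophage or pan-leukocyte levels as covariates, without control mice 3 and 4, and the permutation and fry calls were chosen after seeing the data. With 5 mice per diet and 16513388 to 18653705 counts per library, the number of genes past the threshold moved between 0 and 740 over the alternatives. Where a result moved the cause was not tested.

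The 9 genes kept their direction in all 22 alternatives, and Stra6 stayed past the threshold in 21 of 22, Cryab and Sema3c in 15, Camk2a and Fam19a1 in 14, Gng11 and Slc5a4a in 13 and Dach2 and Rnf19b in 12. The count was 53 with no low-count filter, 316 with DESeq2, 740 with limma-voom, 180 with a surrogate variable, 0 with library size as a covariate, 286 with the macrophage level, 524 with the pan-leukocyte level, 276 without control mice 3 and 4, 16 at an adjusted p under 0.1 and 5 with a log2 change of at least 1. Leaving out 1 mouse gave between 1 and 27. Same-numbered mice are different animals and their residuals correlated between -0.36 and 0.33; the number as a replicate block gave 16 genes, 6 of them shared with the 9. The distance between diets was 0.00283 without control mice 3 and 4 (exact p = 0.0536) and between 0.00193 and 0.00300 with 1 mouse left out, no longer passing without control mouse 4 (exact p = 0.0714) or high-fat mouse 3 (exact p = 0.0556).

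Of the 16 lists, 0 passed with an estimated correlation, 0 by exact permutation of list means and 0 with fry's test for change one way. Fry's test for change in either direction, which compares a list with no other genes, passed 7 of the 16: lipid uptake (adjusted p = 0.0125), fatty acid synthesis (0.0476), glycolysis, hypoxia, interferon and NRF2 (each 0.0415) and macrophages (0.0446). It also passed 7 of the 16 lists that did not pass camera. The adjusted p-values with an estimated correlation, by permutation and with fry one way were 0.420, 0.127 and 0.115 for lipid uptake and skeletal muscle, 0.426, 0.127 and 0.136 for fatty acid synthesis, 0.491, 0.268 and 0.281 for cholesterol, MHC class I and dendritic cells, 0.420, 0.127 and 0.122 for glycolysis and interferon, 0.421, 0.127 and 0.138 for hypoxia, 0.693, 0.552 and 0.586 for oxidative phosphorylation, 0.509, 0.268 and 0.361 for mitochondrial transcripts, 0.693, 0.552 and 0.615 for MYC targets, 0.491, 0.169 and 0.281 for NRF2, 0.491, 0.254 and 0.281 for amino acids, 0.619, 0.470 and 0.481 for pan-leukocyte and 0.420, 0.127 and 0.129 for macrophages. With the macrophage level as a covariate camera's adjusted p was 0.561 for oxidative phosphorylation, 3.8e-06 for pan-leukocyte and 0.00729 for dendritic cells, all reversed, and 0.135 for muscle. Oxidative phosphorylation had 0.845 with the pan-leukocyte level and 0.330 without control mice 3 and 4, where pan-leukocyte (0.799) reversed and dendritic cells (0.422) and muscle (0.0512) no longer passed. MYC targets had 0.190 with a surrogate variable. Counts over the list alone, higher and lower, were 0 and 3 in edgeR, 2 and 5 with DESeq2 and 4 and 4 with limma-voom for fatty acid oxidation, 7 and 5, 7 and 8, and 9 and 7 for chemokines, and 2 and 4, 3 and 5, and 6 and 5 for checkpoint genes. Those higher were 0, 0 and 1 for mitochondrial transcripts, where 7, 7 and 7 were called with the macrophage level, with the pan-leukocyte level and without control mice 3 and 4, and 0, 0 and 2 for muscle, where these 3 alternatives called 1, 1 and 2. In the same order they called, over the list alone, 13, 15 and 14 unfolded protein genes lower against 5 in edgeR, 6, 9 and 5 NRF2 genes lower against 3, 6, 8 and 6 lipid uptake genes lower against 5, 44, 44 and 43 interferon-stimulated genes higher against 29, and 2, 3 and 4 endothelial genes higher against 0. Control mice 3 and 4 lay farthest of the controls toward the high-fat side on each list in this comparison, so these counts are no independent support.

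Lists not past the threshold reversed as follows, by camera's adjusted p unless permutation or fry is named. Chemokines had 0.979 with a surrogate variable and 0.753 by permutation. With the macrophage and pan-leukocyte levels checkpoint genes had 0.542 and 0.895, proliferation 0.375 and 0.440, ribosomal proteins 5.9e-06 and 0.00398 and mesenchymal genes 0.561 and 0.982. Proliferation had 0.984 by permutation and 0.799 without control mice 3 and 4, where ribosomal proteins had 0.0188. Epithelial genes had 0.985 with fry. Fibroblasts had 0.934 with the stricter filter and 0.946 with a surrogate variable. Leaving out 1 mouse gave ranges of 0.00726 to 0.0543 for lipid uptake, 9.3e-06 to 0.300 for oxidative phosphorylation, 0.584 to 0.999 for chemokines, 0.0451 to 0.999 for proliferation, 7.3e-06 to 0.191 for MYC targets, 0.0743 to 0.976 for ribosomal proteins, 0.774 to 0.999 for p53 targets, 0.414 to 0.999 for epithelial genes, 1.7e-05 to 0.146 for pan-leukocyte, 0.200 to 0.939 for fibroblasts and 0.0192 to 0.0916 for muscle.

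Of 2217 values of named genes under alternatives, 1927 kept direction and side of the threshold, 69 fell short of it, 171 newly passed and 50 reversed, none of these past it. With the macrophage level the log2 change was -0.19 for Aldoa, 0.29 for Erap1, 0.17 for H2-Q4, 0.0322 for Socs1, -0.13 for Hspe1, 0.76 for Lcp1, 0.36 for Cd74, 0.40 for H2-Ab1 and 1.89 for Ptprc. With the pan-leukocyte level it was -0.0290 for Aldoa, 0.12 for Erap1, 0.0792 for H2-Q4 and 0.46 for Ptprc, and without control mice 3 and 4 it was -0.0754, 0.17, 0.0686 and 0.69. With limma-voom it was 0.10 for Erap1, 0.0562 for H2-Q4 and -0.0024 for Bcat2, with upper-quartile scaling 0.0019 for H2-Q4, and with library size as a covariate -0.0782 for Clec9a, -0.0395 for B2m and -0.0322 for Mki67. Leaving out 1 mouse gave -0.0586 to 0.14 for Aldoa, -0.0706 to 0.10 for Erap1, -0.0806 to 0.0368 for H2-Q4, -0.12 to 0.0331 for Socs1, -0.0424 to 0.0639 for Bcat2, -0.0514 to 0.51 for Clec9a, -0.0103 to 0.13 for B2m and -0.0273 to 0.0653 for H2-K1.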

Other observations

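All of the tests in this part with leukocyte levels as covariates or without control mice 3 and 4 were chosen only after the results were seen, as were the genes named here.

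Among the 29 interferon-stimulated genes that passed over the list alone were the antiviral genes Oas2, with a log2 change of 1.05, Mx2 (0.95) and Rsad2 (0.82), the ubiquitin-like modifier Isg15 (0.54) and the transcription factor Irf9 (0.54). The macrophage list held the complement genes C1qa (-2.38), C1qb (-2.42) and C1qc (-2.59) and the receptor Csf1r (-2.68). The MHC class II genes H2-Aa (-1.99) and H2-Eb1 (-1.95) moved with them. Cxcl12, a chemokine of stromal cells, had a log2 change of 1.37 and Hspa1b, a stress-induced chaperone, one of 1.36. In edgeR, 188 genes passed under each of the 3 leukocyte alternatives (98 higher, 90 lower), the 9 genes reported among them.

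Across the 10 libraries, 3 relations were computed with permutation p-values. The interferon-stimulated list went with the T and NK cell list (Pearson r = 0.78, p = 0.00701, adjusted 0.0105; Spearman rho = 0.76, p = 0.0151, adjusted 0.0258), with r = 0.74 without the 2 farthest libraries. Its pooled relation with the macrophage list (r = -0.00, p = 0.991, adjusted 0.991; rho = -0.21, p = 0.562, adjusted 0.562; r = -0.30 without the 2 farthest) mixes diets whose means differ in opposite directions and says nothing of the relation within a diet. Xist went with the pan-leukocyte list (r = 0.85, p = 0.00197, adjusted 0.00591; rho = 0.75, p = 0.0172, adjusted 0.0258), with r = 0.59 without the 2 farthest. With 5 mice per diet no correlation is given within a diet, but the orders of the libraries are. Control mice 2, 5, 1, 3 and 4, in that order, had interferon list means of 5.19, 5.28, 5.76, 6.15 and 6.20 log2 CPM, and stood in the same order on the macrophage list (1.49, 1.89, 3.00, 4.17 and 4.43) and on the T and NK cell list (-1.85, -1.44, -0.36, 1.55 and 2.47). High-fat mice 1, 5, 4, 2 and 3 had interferon list means of 6.06, 6.39, 6.41, 6.42 and 6.52 and stood in the same order on the T and NK cell list (-0.54, -0.51, 0.77, 1.99 and 2.13) but not on the macrophage list (0.71, 1.39, 1.22, 2.02 and 1.21). Xist was at 2.17, 2.72, 8.67, 13.5 and 0.739 CPM in control mice 1 to 5 and at 0.362, 2.04, 3.51, 0.527 and 0.467 CPM in high-fat mice 1 to 5.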
